A study of Mus musculus with 4 samples.

How the data were processed

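The series measured polyadenylated RNA of mouse oocytes by Smart-seq2, a full-length cDNA protocol for very small inputs that starts from an oligo-dT primer, followed by library preparation with Tn5 transposase, per the labels' protocols. Each of the 4 libraries was made from 10 oocytes, and each group held 1 library. Control mice carried floxed Dcaf13 alleles on a C57B6 background. Deletion mice carried the same alleles and the Gdf9-Cre transgene, in which the Gdf9 promoter drives Cre recombinase in oocytes from early follicle growth on. Growing oocytes came from mice of about 14 days. Fully grown oocytes came from mice of about 23 days, 48 h after an injection of 5 IU of PMSG, pregnant mare serum gonadotropin, which stimulates follicle growth.

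The deposited values are FPKM, fragments scaled to transcript length and to the number of mapped fragments, with 1 row per gene symbol. The submitters' processing notes name CASAVA 1.8, TopHat2 2.0.11, Bowtie2 2.1.0, Cufflinks 2.2.1 and the genome build mm9, without their roles or settings. The gene models, the handling of strand and of reads with several matches, and any filter are not given in the sources used here. The whole-series table held 23235 rows with 23235 distinct symbols, and the values of the 4 per-sample tables were identical to it. No sequencing depth is stated, and FPKM does not give it. Among low genes a value is close to a whole multiple of what 1 read is worth, so the most common ratio between libraries gives their relative depth. Against the growing control library this was 1.03 for the growing deletion library, 1.01 for the fully grown control library and 1.12 for the fully grown deletion library.

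The symbol column and the value columns of the deposited FPKM table were found to run in different sort orders, and this decided how the values were read. The symbols and their annotation are in alphabetical order that ignores case and hyphens. The values fit the same symbols in byte order, in which digits come before capitals and capitals before lower case letters. In byte order 4113 rows keep their symbol and 19122 rows take another one, often from 1 or 2 rows away. In the tables as deposited the row of Zp1 held a mean of 3995 FPKM, while Gdf9 stood at 3.02, Ooep at 0.0184 and Omt2a at 0, although all are abundant oocyte transcripts. After re-pairing, 3995 FPKM belonged to Zp3, Gdf9 stood at 2450.4, Ooep at 2348 and Omt2a at 616. The median of the 18 oocyte markers was 4.10 FPKM as deposited and 1950.0 after re-pairing. The 13 genes of chromosome Y, which oocytes lack, summed to a mean of 197 FPKM as deposited and to 0.153 after re-pairing. A check without expression markers used the smallest value above 0 of low genes, about the worth of 1 read, which is lower for longer transcripts. Its correlation across genes with transcript length (both as logs) was -0.20 as deposited and -0.42 after re-pairing, and on moved rows -0.13 and -0.40. Of 46 windows of 500 rows, 42 had their strongest correlation at no further shift after re-pairing, against 9 as deposited. All values below therefore use the re-paired table. This pairing is an inference from the values, made after the data were examined, and was not checked with the submitters. The deposited pairing was kept as an alternative where it can be used. The counts of genes past a threshold do not depend on the pairing, and the row of Dcaf13 is the same in both.

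Changes were computed as differences in log2(FPKM + 1), with a pseudocount of 1, a scale that understates the change of low genes. With 1 library per group no comparison of 2 groups has an estimate of error, and no test was run. A fit of genotype and stage without their interaction would leave 1 residual degree of freedom over the 4 libraries. It was not run, since it takes the deletion to act alike at both stages and counts any difference between them as error. A gene was counted as higher or lower by a rule of size fixed before the data were examined: FPKM of 5 or more in at least 1 of the 2 libraries and a change of at least 1 on the log2 scale. The rule compares 2 libraries, not 2 conditions. Genes named in the text were chosen by a rule fixed at the same time. It took Dcaf13, the 8 largest increases and the 8 largest decreases per comparison among genes past the size rule at 20 FPKM or more in 1 of the 2 libraries, without predicted genes, clone-named genes, microRNA and snoRNA genes and pseudogenes, up to 2 members of each gene list per direction, and the 3 most abundant markers of each other cell type. Genes named outside this rule are pointed out, apart from the oocyte genes that illustrate the pairing above. The design also named a model for replicated libraries, which the table did not allow.

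For each of 19 gene lists fixed before the data were examined, members at 1 FPKM or more in at least 1 of the 4 libraries were read as measured. The list's median change was placed among 10000 random lists of the same size matched on mean log2(FPKM + 1) in 20 bins. A list is said to stand apart when its percentile is below 0.5 or above 99.5. This describes these libraries and is not a test of the conditions. Of the 76 readings, 9 stood apart, where lists of genes that vary independently would give 0.760. Members of a list can vary together and the comparisons share libraries, so 9 beside 0.760 is not a test.

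The alternatives chosen before the data were examined were a pseudocount of 0.1, an FPKM minimum of 1, no minimum, each library rescaled to a total of 1000000, rescaling by the median ratio to the geometric mean over 6465 genes, random lists not matched on expression, and list members with a mean of 5 FPKM or more. Chosen afterwards were the deposited pairing and the removal of a quadratic trend of each change on transcript GC content and log length. A first version of the trend removal, run while the data were explored, used only directly matched symbols, no interaction term and a fit per comparison. It gave 682 genes over growth in the deletion and 252 in controls, and is otherwise not reported. GC and length came from the longest GENCODE M21 transcript of each symbol, protein-coding ones preferred, and were found for 22780 symbols, older symbols included. That annotation is on GRCm38, so none of its coordinates are printed. Coordinates below are those of the deposited table on mm9, with starts raised by 1 to count from 1, since end minus start equals the reference gene length for 8468 genes.

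The steps were tested on simulated data, with 50 genes changed per fold size and a noise SD scaled from the median size of change in each comparison. All genes had the same SD, without extra noise or lost transcripts among low genes. The changed genes were drawn from well above the FPKM minimum. The shares below therefore describe the rule under simple noise and are not rates of false or missed calls in these libraries. For growing deletion against growing control, 54.0% of genes changed 2-fold, 98.0% of genes changed 3-fold and 100% of genes changed 4-fold were recovered, and 51 of 7495 unchanged genes passed the rule. For fully grown deletion against fully grown control these were 42.0%, 90.0% and 98.0%, with 17 of 7088 unchanged genes. For growth in controls they were 42.0%, 90.0% and 100%, with 14 of 7468, and for growth in the deletion 42.0%, 84.0% and 98.0%, with 227 of 7748. For the list percentiles, 16 of a first 200 unchanged random lists fell outside the middle 95%. The number of lists was then raised to 1000, of which 54 fell outside. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1 were used, with matplotlib 3.10.9 for figures.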

Results

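RNA of mouse oocytes was measured at 2 stages of growth, with and without deletion of Dcaf13 in the oocyte. The gene encodes a nucleolar protein of ribosome assembly that also acts as a substrate receptor of the CRL4 ubiquitin ligase. The 4 groups were growing control, growing deletion, fully grown control and fully grown deletion oocytes, with 1 library of 10 oocytes each. There were no replicates within a group, so every value below is that of a single library, and no test was run. Summed FPKM was 649397 in the growing control library, 665945 in growing deletion, 669104 in fully grown control and 678437 in fully grown deletion. Genes at 1 FPKM or more numbered 10928, 11048, 10500.0 and 10469 in the same order. The 18 oocyte markers were at 1 FPKM or more in at least 1 library, with medians per library between 1778 and 1910 FPKM.

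**Figure D1:**
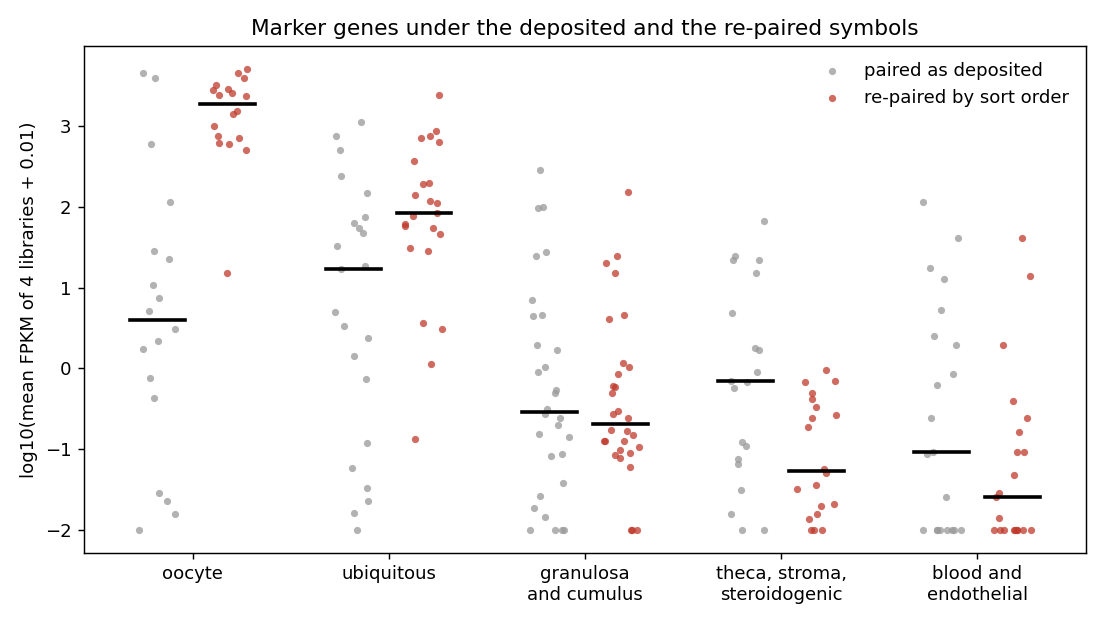
Each point is a marker gene, with log10 of its mean FPKM over the 4 libraries plus 0.01, under the symbols as deposited and as re-paired by sort order. The median of the 18 oocyte markers is 4.10 FPKM as deposited and 1950.0 FPKM after re-pairing.

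Dcaf13 (chromosome 15, plus strand, 38944420 to 38978401, mm9) was lower in both deletion libraries. It stood at 96.1 FPKM in the growing control and 38.9 in the growing deletion library, which is 40.5% of control and a change of -1.28 in log2(FPKM + 1). In fully grown oocytes it stood at 160.2 and 64.0 FPKM, which is 39.95% of control and a change of -1.31. Its row is the same under either pairing of symbols and values. An FPKM of the whole gene does not show whether the floxed part was lost. The 6 expressed neighbours looked at were chosen by position, outside the rule for names, and are given after their values were seen. None was past the size rule, with changes from -0.84 (Dpys) to 0.58 (Klf10) in growing and from -0.40 (Azin1) to 0.16 (Klf10) in fully grown oocytes.

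The comparison of growing deletion with growing control oocytes addresses what deletion of Dcaf13 does during oocyte growth. Ribosomal protein genes were slightly higher as a group in the deletion library, and so were genes of large subunit assembly, while replication-dependent histones had a median above 0 with members on both sides. The single genes with the largest differences were of mixed function. Hmgn3, which encodes a nucleosome-binding protein, stood at 44.3 FPKM against 6.90 in control, and the growth factor gene Pdgfa at 25.6 against 5.19. Agpat9, an acyltransferase of glycerolipid synthesis, stood at 2.23 against 21.8 FPKM, and Nmu, which encodes the peptide neuromedin U, at 3.56 against 28.7. Of 8010 genes at the minimum, 210 were higher and 201 lower by the size rule. Further increases were Baiap2l2 (2.09), the keratin gene Krt73 (2.03), Cisd3 (1.75) and Tmem160 (1.63), as changes in log2(FPKM + 1), and Vrk3 stood at 31.7 against 8.41 FPKM. Scarna3a, a small Cajal body RNA gene, was at 23.7 FPKM and listed at 0 in the other 3 libraries. Further decreases were Rgn (-2.48), which encodes the calcium-binding protein regucalcin, the defensin gene Defb41 (-2.13), Calr3 (-2.09), a paralog of calreticulin, Mbd3l2 (-1.81) and Bmp5 (-1.78), and the potassium channel gene Kcnn2 stood at 8.14 against 30.9 FPKM.

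Of the 85 ribosomal protein genes measured, 81 were above their growing control value, with a median change of 0.28 at percentile 100 of random lists, although only Rpl34 (1.14) was past the size rule. Of the 50 genes of 60S assembly, 40 were above control with a median of 0.25 (percentile 99.9) and none past the rule. The 30 histone genes had a median of 0.45 (percentile 99.98), with 18 above control, 4 higher and 1 lower by the rule. The list took symbols by pattern alone, and how well a poly(A)-primed library captures its RNAs was not examined. Abundant members went both ways: Hist1h2bc (244 against 256 FPKM in control) and Hist1h2aa (48.7 against 59.4) were below control, and Hist1h1a (36.5 against 17.6) and Hist1h4h (33.4 against 15.6) were higher by the rule, with Hist1h2bc, Hist1h2aa and Hist1h4h named after their values were seen. They included Hist3h2a (1.08), the linker histone Hist1h1c (1.06) and, lower, Hist2h2bb (-1.15). Single members of lists that did not stand apart were past the rule as well. Both Ubtf (1.20) and Taf1c (1.27), factors of RNA polymerase I transcription, were higher, as were Eif2b5 (1.21), the immunoproteasome gene Psmb10 (2.02), Uqcrc1 (1.11) and Cox8c (1.16) of oxidative phosphorylation, Tm7sf2 (1.01) of sterol synthesis and the stress response factor Xbp1 (1.01). Lower were Cox6a2 (-1.21), the maternal effect gene Sebox (-1.05) and Mei4, a gene of meiotic recombination, at 1.22 against 6.76 FPKM. Across genes the change went with transcript GC content (Spearman's rho 0.37), and after removal of the GC and length trend the ribosomal protein median was 0.17 in place of 0.28 and 129 genes in place of 210 were higher, without Rpl34 (0.96), Uqcrc1 (0.86), Taf1c (0.87), Tm7sf2 (0.79), Xbp1 (0.92) and Hist1h1c (0.90), while Tm7sf2 (0.96) and Xbp1 (0.97) also missed the rule with median-ratio rescaling. The 60S reading fell short of standing apart with unmatched lists, with members of 5 FPKM or more and with the deposited pairing, and the histone reading with members of 5 FPKM or more.

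The comparison of fully grown deletion with fully grown control oocytes addresses the same question at the end of growth. Ribosomal protein genes were again slightly higher as a group in the deletion library, while the measured 2-cell stage genes were lower, with a median of -0.25 (percentile 1.87) in the growing comparison. Slc39a8, which encodes a zinc transporter (chromosome 3, plus strand, 135488455 to 135551536, mm9), stood at 9.39 FPKM against 40.8 in control. Krt73 was at 20.8 against 6.76 FPKM, and Snhg1, a host gene of small nucleolar RNAs, at 84.5 against 30.4. Of 7413 genes at the minimum, 80 were higher and 81 lower by the size rule. Small nucleolar RNA genes, a class picked out after the values were seen, had 24 members at the minimum. They made up 4 of the 80 and 11 of the 81. Further increases were the tubulin gene Tuba3b (1.39), Hist1h4d (1.34), the cytokine receptor gene Crlf2 (1.31), the claudin gene Cldn15 (1.30), Rpl34 (1.19) and Tmem205 (1.12). Further decreases were the transcription factor gene Batf3 (-1.48), Rgn (-1.47), Fam84a (-1.43), Dhrs3 (-1.41), a retinaldehyde reductase, Fam113b (-1.24) and the protease inhibitor gene Serpinb12 (-1.24).

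Of the 85 ribosomal protein genes, 74 were above their fully grown control value, with a median change of 0.24 (percentile 100), and Rpl34 was again the only member past the rule. None of the 10 measured 2-cell stage genes was above control, and their median change was -0.45 (percentile 0), with none past the rule. Most of them were under 5 FPKM in both fully grown libraries, such as Zscan4d at 2.03 against 3.41 FPKM. Sp110 (305 against 343 FPKM) and Arg2 (196 against 240) were abundant. These genes were picked after their values were seen. Oxidative phosphorylation had 2 members higher, Cox7a1 (2.01) and Cox8c (1.05). The histones had Hist1h4d and Hist1h1a (1.05) higher. Sycp1 (-1.09), a component of the synaptonemal complex, was lower. Cox8c (0.99) and Hist1h1a (0.99) were no longer past the rule after rescaling by the median ratio, nor Crlf2 (0.90) and Sycp1 (-0.86) after removal of the GC and length trend. The 2-cell reading had percentile 1.52 with the deposited pairing, and 0.69 among genes matched on expression, GC and length.

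The 2 deletion comparisons share no library, so genes past the rule in both were counted. There were 17 genes higher at both stages, where independent lists would share 0.837, and 24 lower at both, where independent lists would share 1.25. Higher at both stages were, among the named genes, Krt73, Baiap2l2, Rpl34, Cox8c and Hist1h1a. Lower at both stages were Dcaf13, Agpat9, Rgn, Slc39a8, Batf3, Fam113b and Serpinb12. Rpl34 (chromosome 3, minus strand, 130429749 to 130433226, mm9) went from 88.0 to 195.6 FPKM in growing and from 87.8 to 202.1 FPKM in fully grown oocytes, each from control to deletion. Of the genes past the rule, Tuba3b and Mir3968 (the latter outside the rule for names and given after its values were seen) lay in opposite directions at the 2 stages. Across the 7188 genes at the minimum in both comparisons, Pearson's r was 0.44 and Spearman's rho 0.47. Genes are not independent replicates, and both comparisons share the trend with GC content (rho 0.37 and 0.41). The number higher at both stages was 26 with a pseudocount of 0.1, 11 with median-ratio rescaling and 9 after removal of the GC and length trend.

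**Figure D2:**
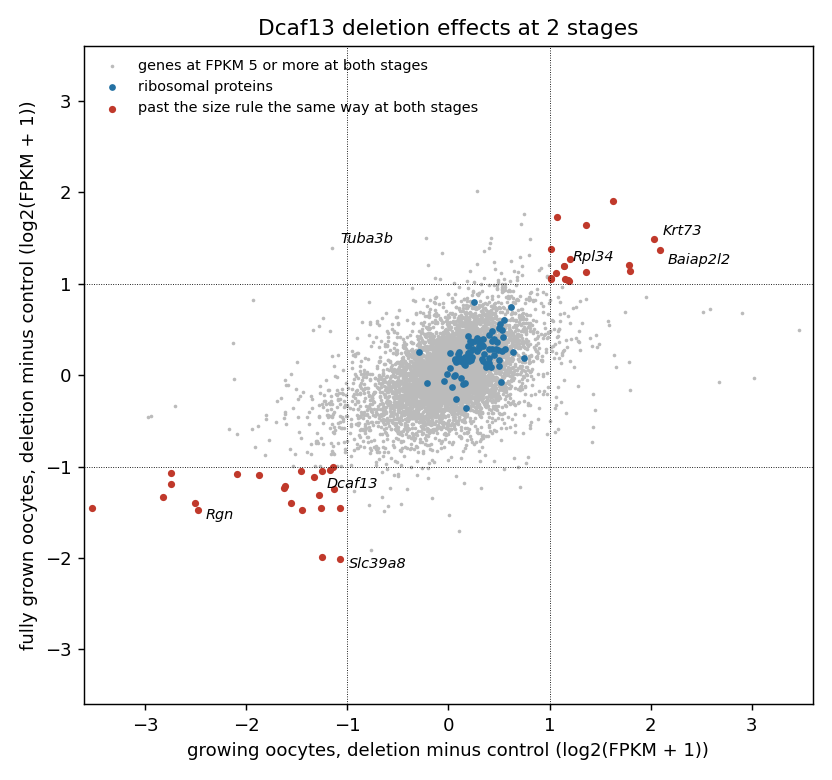
Each point is 1 of the 7188 genes at 5 FPKM or more at both stages, with its change in log2(FPKM + 1) from control to deletion in growing oocytes (x axis) and fully grown oocytes (y axis), and 7 genes lie outside the axes. Blue points are 84 ribosomal protein genes, which lie mostly above 0 on both axes, and red points are the 41 genes past the size rule the same way at both stages.

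**Figure D3:**
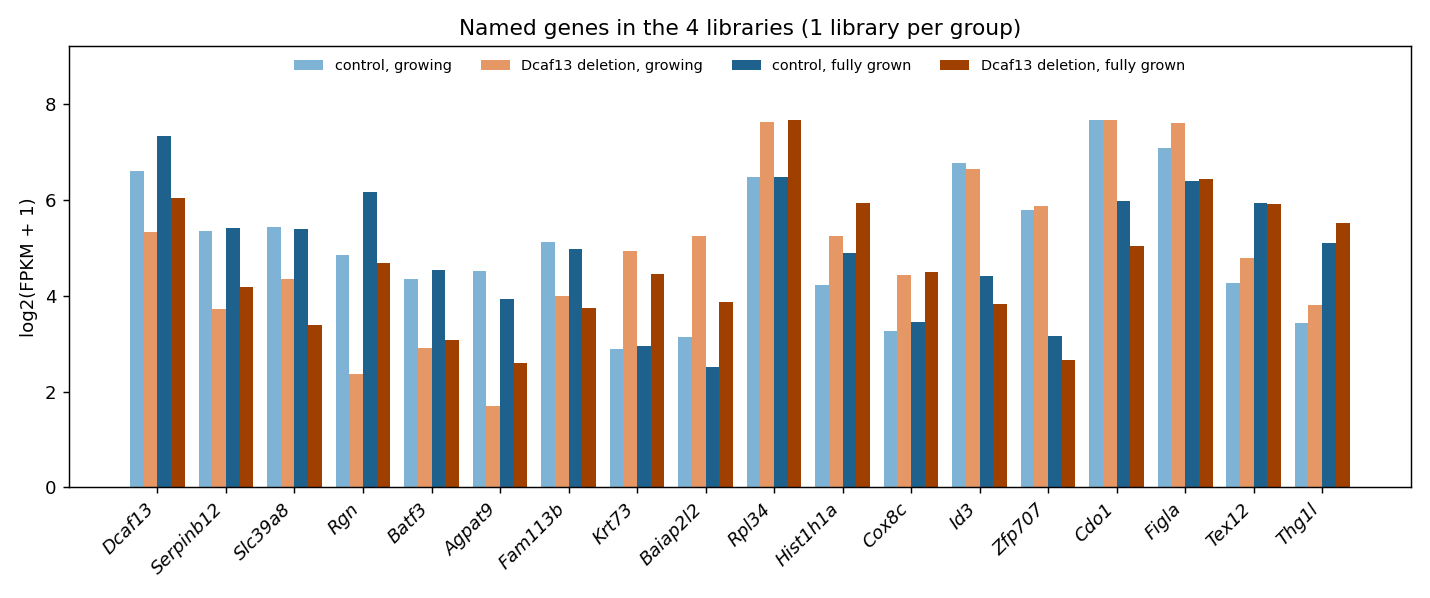
Bars give log2(FPKM + 1) of named genes in the 4 libraries, 1 library per group. Dcaf13, Rgn and Slc39a8 are lower in the deletion library at both stages, and Rpl34 and Krt73 are higher at both.

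The comparison of fully grown with growing control oocytes describes oocyte growth in controls. Stage, age of the mice and PMSG, given only for the fully grown groups, cannot be told apart in either genotype. More genes were lower than higher at the end of growth, and the genes of oocyte growth and the zona pellucida and the maternal effect genes were lower as groups. FPKM is scaled to the mapped fragments of each library. Lower therefore means a lower share in either genotype, and the amount of RNA per oocyte is not known from these values. Id3, an inhibitor of helix-loop-helix transcription factors, stood at 20.4 FPKM against 106.8 in growing oocytes, and Cdo1, a cysteine dioxygenase, at 61.5 against 200.9. Tex12, a component of the synaptonemal complex, was at 59.8 against 18.04 FPKM. Of 7661 genes at the minimum, 85 were higher and 235 lower by the size rule, and 21 of the 85 were small nucleolar RNA genes, a class picked out after the values were seen. Further increases were Snhg9 (2.62), Thg1l (1.66), Mef2b (1.41), Rgn (1.30), Ppil3 (1.19), Nhedc1 (1.17) and Fam25c (1.12). Further decreases were Zfp707 (-2.62), Gimap1 (-2.29), the transcription factor gene Snai1 (-1.97), Fxyd6 (-1.89), Yrdc (-1.82), Ldhc (-1.75), a germ cell lactate dehydrogenase, and Cdo1 (-1.69). The 25 genes of oocyte growth and zona had a median change of -0.23 (percentile 0.03) with none past the rule. The 44 maternal effect genes had a median of -0.12 (percentile 0.20), with the histone demethylase gene Kdm1b (-1.04) lower. Members of other lists that were lower included Rpl9 (-1.18), Rpl10l (-1.17), Bop1 (-1.36), Ubtf (-1.45), Polr1c (-1.03), Psmd13 (-1.29), Uqcrc1 (-1.23), Cox7a1 (-1.15), Pmvk (-1.30), Patl2 (-1.20), Pabpc1 (-1.05) and Chac1 (-1.22). Hist1h2ba (1.68), Hist1h3g (1.14) and Tex11 (1.12) were higher. Neither list stood apart after removal of the GC and length trend (percentiles 8.95 and 3.57), with unmatched lists or with the deposited pairing, while both did among genes matched on expression, GC and length (0.010 and 0.11). Fam25c (0.53) and Hist1h3g (0.95) missed the rule without that trend, and Polr1c (-0.997) with median-ratio rescaling.

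The comparison of fully grown with growing deletion oocytes describes growth of the deletion oocytes, in which Dcaf13 FPKM was lower but not absent. It had more genes past the rule than growth in controls, again mostly lower ones. It shares the growing deletion library with the comparison of growing deletion and growing control oocytes, so these comparisons are not independent. Of the genes higher in growing deletion than in growing control oocytes, 129 were lower over growth in the deletion. Of the genes lower there, 69 were higher over growth in the deletion. Zfp771 stood at 2.90 FPKM against 37.4 in growing deletion oocytes, and the homeobox gene Gsc at 2.72 against 23.4. Nmu was at 32.2 against 3.56 FPKM and Rgn at 24.6 against 4.18, both genes that were low in the growing deletion library. Of 7957 genes at the minimum, 215 were higher and 696 lower. Further increases were Olfr288 (2.44), Gstk1 (2.43), the augmin gene Haus7 (2.26), Fam162b (2.23), Defb41 (2.11) and Tuba3b (1.91). Further decreases were Zfp707 (-3.21), Id3 (-2.81), the homeobox gene Tgif1 (-2.74), Crym (-2.72) and Cdo1 (-2.62), and Scarna3a was listed at 0. Genes of oocyte growth and zona had a median change of -0.32 (percentile 0.02), with Tbpl2 (-1.31) and Figla (-1.17), both oocyte transcription regulators, lower. Maternal effect genes had a median of -0.18 (percentile 0.05), with Kdm1b (-1.22) and the RNA-binding protein gene Ythdf2 (-1.15) lower. RNA polymerase I transcription had 4 members lower, among them Ubtf (-2.48) and Taf1c (-1.41). Cul4a (-1.22) and Crbn (-1.02), both of the CRL4 ligase, were lower, as were the cell cycle kinase gene Wee1 at 5.41 against 21.3 FPKM, Zfp36l2 (-1.78), Nop2 (-1.76), Nob1 (-1.62), Psmb5 (-1.26) and Uqcrc1 (-2.21). Hist1h4c (1.70), Mei4 (2.05), Ccnb3 (1.20) and Slc7a11 (1.18) were higher. Neither list stood apart after removal of the GC and length trend (percentiles 2.5 and 3.09), with unmatched lists or with the deposited pairing, while both did among genes matched on expression, GC and length (0 and 0.010). Slc7a11 (0.96) missed the rule without that trend, and Crbn (-0.9996) with median-ratio rescaling.

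Growth changes in control and deletion oocytes share no library either. Of the 85 genes higher over growth in controls, with a median change of 1.73, 58 also lay above 0 in the deletion, where their median was 0.80, and 32 were past the rule. Small nucleolar RNA genes, whose FPKM is imprecise here, made up 21 of the 85 and weigh on these values. Some, such as Snord100, were listed at 0 in both deletion libraries and so had no change there. Others, such as Snord37, were past the rule in both genotypes. Both were picked after their values were seen. Of the 235 genes lower in controls, with a median of -1.22, 225 also lay below 0 in the deletion, where their median was -1.41, and 163 were past the rule. In the reverse choice, the 215 genes higher in the deletion had a median of 1.34 there and 0.44 in controls, and the 696 lower genes -1.35 and -0.77. Id3, Cdo1, Zfp707, Ubtf, Uqcrc1 and Kdm1b were among the genes lower in both, and Rgn, Tex12, Thg1l and Gstk1 among those higher in both. Across 7383 genes Pearson's r was 0.68 and Spearman's rho 0.66.

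Percentiles of the lists are given here in the order growing deletion against control, fully grown deletion against control, growth in controls and growth in the deletion. The lists that stood apart somewhere lay at 100, 100, 96.3 and 67.0 (ribosomal proteins), 99.9, 88.6, 76.1 and 15.5 (60S assembly), 99.98, 89.4, 95.1 and 75.6 (histones), 1.87, 0, 73.95 and 17.0 (2-cell genes), 21.2, 66.0, 0.03 and 0.02 (oocyte growth and zona) and 23.8, 8.68, 0.20 and 0.05 (maternal effect). The other lists stood apart in no comparison as mainly read, although some did under an alternative. Genes of 18S processing (55 measured) lay at 99.06, 98.26, 88.4 and 53.4, and genes of oxidative phosphorylation (84) at 98.6, 99.48, 13.1 and 40.6. Genes of RNA polymerase I transcription (19) lay at 70.9, 12.9, 68.1 and 4.98, translation factors (52) at 90.6, 69.6, 75.02 and 33.7, and the proteasome (41) at 47.1, 51.7, 91.7 and 81.0. Sterol synthesis (18) lay at 84.2, 72.8, 26.7 and 10.1, and maternal mRNA polyadenylation and decay (48) at 9.68, 65.8, 99.02 and 95.01. Meiotic resumption (56) lay at 24.0, 45.6, 75.3 and 66.5, the methylation machinery (37) at 75.9, 98.2, 6.31 and 17.5, and the CRL4 ligase (34) at 90.9, 64.8, 7.30 and 16.4. The p53 targets (26) lay at 84.7, 33.3, 87.5 and 73.1, the stress and unfolded protein response (37) at 67.6, 99.26, 0.87 and 22.1, and recombination genes (24) at 50.1, 17.5, 41.0 and 18.4. Among them, Aen (-1.12) of the p53 targets, Cbx3 (-1.33) of the methylation machinery and Trip13 (-1.48) of recombination were lower over growth in the deletion.

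**Figure D4:**
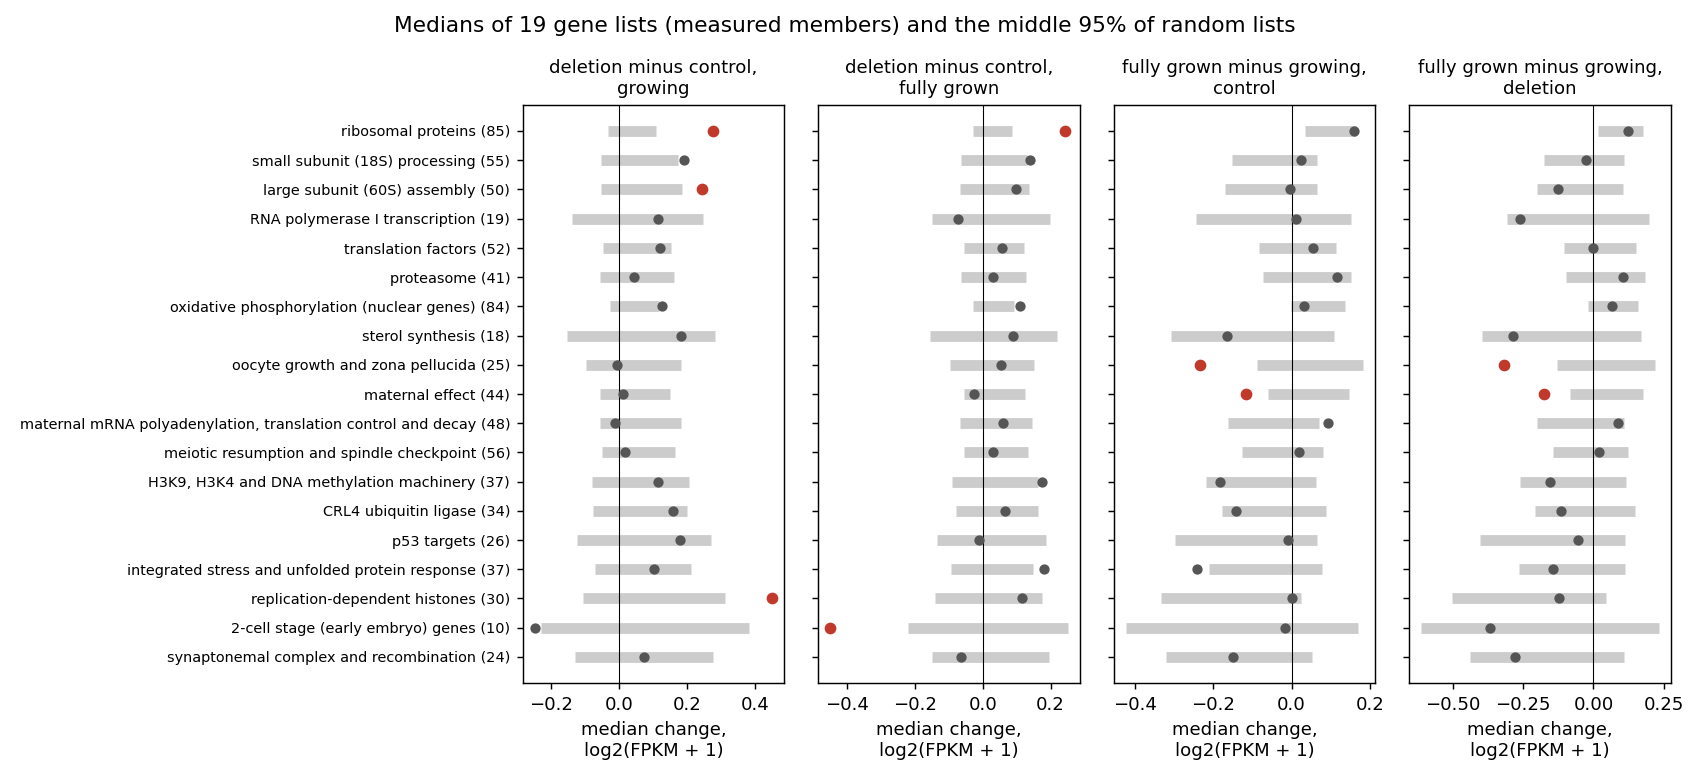
Points are the median changes in log2(FPKM + 1) of 19 gene lists in the 4 comparisons, and bars the middle 95% of random lists matched on expression. Red points mark the 9 of 76 readings that stand apart, where lists of genes that vary independently would give 0.760.

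Most markers of other ovarian cells were under 1 FPKM. Of 30 granulosa and cumulus markers 10 reached 1 FPKM in a library, of 20 theca and stroma markers 1, and of 21 blood and endothelial markers 4. The granulosa markers summed to 245 FPKM in growing control, 212 in growing deletion, 247 in fully grown control and 206 in fully grown deletion oocytes, mostly from Serpine2 at 129.8 to 164 FPKM. The others among the 3 most abundant were Esr2 (28.9 and 13.7 FPKM in growing control and deletion, 35.0 and 20.7 in fully grown ones) and Bmpr1b. Theca and stroma markers, led by Hsd3b1, Sparc and Dcn, summed to 5.44, 4.66, 3.41 and 3.75 FPKM. Blood and endothelial markers summed to 87.4, 40.1, 49.1 and 53.8 FPKM, with C1qb alone at 72.1, 23.4, 35.1 and 32.4 and then Pecam1 and Cd68. Beside the ribosomal protein readings, the summed somatic markers with a mean under 1 FPKM were 14.2 in growing control, 8.82 in growing deletion, 6.28 in fully grown control and 9.99 in fully grown deletion oocytes.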

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

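No tests of an explanation were run in this part. Tuba3b, a tubulin gene, stood out because its change from control to deletion was past the size rule in opposite directions at the 2 stages. The change in log2(FPKM + 1) was -1.15 in growing oocytes, from 30.2 to 13.04 FPKM, and 1.39 in fully grown oocytes, from 19.1 to 51.6 FPKM. The difference between the stages was not tested, since each group held 1 library.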

How the results depend on the processing

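The removal of the GC and length trend and the deposited pairing were chosen after the data were seen. With 1 library per group no alternative can leave out a library. The deposited tables hold no FPKM intervals and no repeated symbols, so those alternatives were not run. The deposited pairing was run only for Dcaf13 and the lists, because it gives most other genes the value of another row. If the re-pairing holds, this is so for many list members too, and a list reading as deposited is partly that of other genes. Dcaf13 stayed lower past the size rule at both stages in all 5 alternatives run for it. For the deposited pairing, which leaves its row unchanged, and the pseudocount of 0.1, which can only enlarge its change, this was fixed in advance. With an FPKM minimum of 1 or none, which give equal counts because a change of 1 needs at least 1 FPKM, growing deletion against control had 370.0 genes higher and 330.0 lower, and fully grown deletion against control 143 and 133. Growth in controls had 133 higher and 425 lower, and growth in the deletion 355 and 1101. Higher at both stages in the deletion were 33, higher over growth in both genotypes 54 and lower in both 285. More genes are admitted by construction. The number higher at both stages was 26 with a pseudocount of 0.1, 11 with median-ratio rescaling and 9 without the GC and length trend, where 129 genes were higher in growing deletion oocytes. The cause was not tested. For list medians with percentiles, 60S assembly in the growing deletion comparison had 0.25 (99.4) with unmatched lists, 0.18 (96.8) with members of 5 FPKM or more and 0.18 (93.9) as deposited. Oocyte growth and zona in control growth had -0.23 (8.54) unmatched, -0.12 (8.95) without the trend and -0.071 (45.5) as deposited, and in deletion growth -0.32 (6.68), -0.13 (2.5) and -0.18 (22.1). Maternal effect genes in control growth had -0.12 (43.2), -0.12 (3.57) and -0.16 (6.63), and in deletion growth -0.18 (25.6), -0.0815 (3.09) and -0.10 (26.5), in the same order. Histones in the growing deletion comparison had 0.42 (99.4) with members of 5 FPKM or more, and 2-cell genes in the fully grown one -0.22 (1.52) as deposited. The cause was not tested. All 76 list readings kept whether they stood apart with a pseudocount of 0.1 and with both rescalings. Medians of lists that did not stand apart crossed 0 in 12 readings with median-ratio rescaling, 7 with a total of 1000000, 9 without the trend, 10 of 72 with members of 5 FPKM or more and 14 as deposited. Of 133 named gene readings, 121 stayed on their side of the size rule without the trend and 127 with median-ratio rescaling. All 133 did with rescaling to a total of 1000000. All 133 also did with a pseudocount of 0.1 and both lower FPKM minimums, but this was fixed in advance. The named genes were chosen as past the rule, and these settings can only enlarge a change or admit more genes. No list that stood apart and no named gene changed direction. List readings that stood apart only under an alternative were 4 without the trend, 4 with members of 5 FPKM or more, 5 with unmatched lists and 4 as deposited. Among them were 18S processing in the growing deletion comparison (99.8 without the trend), ribosomal proteins over growth in controls and in the deletion (100 and 99.95 unmatched) and oxidative phosphorylation in the fully grown deletion comparison under 3 alternatives. Oxidative phosphorylation over growth in controls did so at opposite ends, at 99.51 unmatched and 0 without the trend.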

Other observations

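Chosen only after the result was seen were the small nucleolar RNA and X chromosome counts, the tests of pairing and cell type, of somatic RNA, of GC content and length for the growth counts and of lost transcripts. Small nucleolar and Cajal body RNA genes were mostly low or listed at 0 in the growing libraries. All 21 at the minimum over growth in controls were higher, as were 12 of 15 in the deletion, with only Scarna3a lower. Snord37 was listed at 0 in both growing libraries and stood at 1414 and 1380.3 FPKM in fully grown control and deletion oocytes. Snora47 went from 6.42 to 233 FPKM in controls and from 10.6 to 124 in the deletion. Between the growing libraries 5 of 6 were higher in the deletion and none lower, with a median change of 2.96, and between the fully grown libraries 4 of 24 were higher and 11 lower, with a median of -0.51, where Snord100 stood at 105.1 FPKM in control and was listed at 0 in the deletion. Host genes did not move alike: Snhg9 stood at 6.80 and 47.0 FPKM in growing and fully grown controls, Snhg1 at 30.5 and 30.4 and Snhg6 at 212 and 111. These genes are very short and their RNAs lack poly(A) tails, so their FPKM from a library primed on poly(A) is imprecise.

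Genes on chromosome X past the size rule in the deletion were counted, with microRNA and small nucleolar RNA genes included. In growing oocytes 13 of 236 were lower, 5.51% against 2.51% of all genes, and in fully grown oocytes 9 of 222, 4.05% against 1.09%. Higher were 6 of 236 (2.54% against 2.62%) in growing and 5 of 222 (2.25% against 1.08%) in fully grown oocytes. The next chromosome, 15, had 4.75% and 2.32%. Lower at both stages were Rgn, Tmsb15b2, Gm8817 and 1700042B14Rik. No test was run, since the chromosome was picked from all of them by eye.

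In the tables as deposited, oocyte genes were near 0 and chromosome Y genes were not. Libraries from other cells than oocytes are argued against if the re-pairing holds, since 55 oocyte growth and maternal effect genes that had no part in choosing it have a median of 114 FPKM after it, against 83.2 for ubiquitous genes, and 3.91 as deposited. This took the place of a first test on the 18 oocyte markers (1950.0 FPKM), which had helped to choose the re-pairing. A difference in sort order between symbols and values is consistent with the relation of the smallest values to transcript length, which was strongest at no shift in 42 of 46 windows after re-pairing and in 9 as deposited.

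Ribosomal protein genes were higher in both deletion libraries. GC content and transcript length as the whole cause are argued against at both stages, since the list stood at percentile 100 in growing and 100 in fully grown oocytes among the nearest genes in expression, GC and length, tests written before their results were seen, although removal of the trend took the median from 0.28 to 0.17 in growing oocytes (0.24 to 0.26 in fully grown ones). The low somatic markers had a ratio of deletion to control of 0.62 in growing oocytes, so they showed no excess of somatic RNA. The ratio cannot exclude such RNA, since these markers have a mean under 1 FPKM and each group 1 library. Their sum was 14.2 FPKM in growing and 6.28 in fully grown controls. The test first covered both stages together, which would have left it undecided. It was split by stage after the ratios were seen. Somatic RNA is left open in fully grown oocytes, where the ratio was 1.59. The excess behind it was only 3.71 FPKM, beside 10454 for the ribosomal proteins. All somatic markers together were lower by 35.7 FPKM, mostly through genes with a high baseline. Amh and Krt18 were listed at 0 in both fully grown libraries, and other low markers went both ways. Inhba stood at 1.11 FPKM in fully grown deletion against 0.23 in control oocytes, and Kdr at 0.043 against 0.27. These genes are outside the rule for names and were picked after their values were seen. A bound on the excess, set after the values were known, was dropped because it rests on an assumed profile of the somatic cells. An effect of the deletion and reads shared with ribosomal pseudogenes stay open and untested.

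Growth had 911 genes past the size rule in the deletion and 320 in controls. GC content and length as the whole cause are argued against. The ratio of the counts was 2.56 after removal of the trend (2.71 in its first version). Loss of abundant transcripts from 1 deletion library alone is argued against too. At most 3 genes at 20 FPKM or more in all other libraries were under 5 in a deletion library. Partial losses, losses of less abundant genes and losses shared by both deletion libraries were not covered by this count. A departure of the growing deletion library alone is consistent with 463 genes between fully grown deletion and growing control oocytes, in a test written before its result was seen whose limit was 1.5 times the 320.0 of controls, a limit that 463 comes close to. Fully grown control against growing deletion oocytes gave 1224 genes. Whether that library departs through the deletion, its animals or its preparation stays open, since the group had 1 library.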
